A study of Sus scrofa with 9 samples.

How the data were processed

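Gene counts from RNA sequencing of 9 libraries of primary Göttingen minipig myoblasts were analysed, 3 with inducible human DUX4, 3 with inducible pig DUXC and 3 with inducible GFP, all in 1 µg/mL doxycycline for 16 h. The libraries were made with a stranded kit for poly(A) RNA per the labels. The deposited values are raw read counts per gene, and per the labels the authors called reads with CASAVA 1.9, trimmed them with Trim Galore, used genome build Sscrofa11.1 and counted reads per gene with featureCounts. The column headers name the aligner Subread. Versions other than that of CASAVA, the annotation release and the strand setting of the counting are not given in the sources used here. The counts were used as deposited, with no other scaling by the authors.

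The table has 27339 genes, of which 3855 had no count in any library. Total counts ranged from 36580573 to 44420895 per library, so that 3 counts over the libraries of a group, the floor used for a gene without counts, correspond to 0.0253 CPM with GFP, 0.0243 with DUX4 and 0.0253 with DUXC. Positions were taken from RefSeq for the same assembly, in which 26838 genes (98.2%) matched by symbol, and the unmatched genes held 0.156% of the counts. Symbols starting with LOC, which are locus identifiers, made up 9918 genes, 2367 of them tested. Of 265 named genes, 64 overlap the span of another gene, and their counts may hold reads of the other strand. No gene of the table carries the name of a transgene, and none of KDM4E, TRIM43, KHDC1L, MBD3L2, PRAMEF12, TPRX1 and DUXB is used here.

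Counts were normalised with TMM factors (0.979 to 0.987 with DUX4, 1.05 to 1.06 with DUXC and 0.960 to 0.974 with GFP), and normalised counts (CPM) were scaled to the TMM-adjusted library size. Genes were filtered with filterByExpr by group, which left 15956 and removed 11383. A gene scarce with GFP can pass this filter only through its counts with a transgene. List members scarce in every group were therefore not tested, and shares of raised members cover tested members only. All 9 libraries were fitted together by group in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood pipeline and robust estimation, and 3 contrasts were tested with its two-sided F test: DUX4 against GFP, DUXC against GFP and DUX4 against DUXC. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The common dispersion was 0.00114, a coefficient of variation of 3.38% between libraries of a group. Libraries of the same group differed beyond sampling noise in every pair, with a chi-square per degree of freedom of 2.66 to 18.6. The residuals of libraries with the same number in different groups had correlations of -0.0258 to 0.0318, so the numbers do not pair the libraries and no block was used. With 3 libraries against 3, an exact permutation test cannot give a p below 0.1, and none is reported for a gene.

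Gene lists, comparisons and the rule for named genes were chosen before the data were examined. Named are, for each transgene against GFP, the 10 largest positive and 10 most negative log2 fold changes among genes that passed, had a symbol of their own and at least 1 CPM in the higher group and did not overlap between groups. Also named are the 8 largest in each direction between the transgenes, up to 4 members of each list by smallest p and a fixed set of embryonic, myogenic and dystrophy genes. Where 5 or fewer members of a list moved one way, those outside this rule are named too, except for 1 gene that is not reported here, and these were chosen after their values were seen. Each list was tested for standing apart from other genes with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. Of 32 lists 30 were tested: the PRAME family had 1 member and the mitochondrially encoded genes none. Fold changes of named genes against a group without counts are bounds against the floor, those against a group with 1 to 3 counts are ratios with 95% intervals, and others are fitted values. Ranks and the numbers of genes changed at least 2-fold or 8-fold, with their overlaps and runs, use fitted values for all genes. Camera with a preset correlation and the fold changes fitted for genes near the floor depend on these settings.

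Overlaps of the lists of the 2 transgenes were set against independent lists (the product of their sizes over 15956) and against 20 simulations of unchanged groups that share 3 controls. The pipeline was tested on simulated data with 14254 genes per comparison, where it found 92.4% to 92.5% of changes of log2 0.5 and 100% of changes of log2 1 and 3, and called 20, 23 and 17 of 14054 unchanged genes. The changes were set in few genes, all of at least 1 CPM with GFP. The simulation therefore does not cover genes near the floor or the scaling of data in which most genes change. Neighbouring raised genes were counted in the order of the 15659 tested genes with a position on a chromosome, so genes below the filter may lie between 2 neighbours. The counts were compared with 100000 draws of as many genes matched on the GFP level in 10 strata, a one-sided permutation test. Alternatives tried were DESeq2's size factors, library size alone, other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, fits of 2 groups, a threshold of 0.01 and minimum fold changes.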

Results

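Messenger RNA was sequenced from 9 libraries of primary Göttingen minipig myoblasts, the proliferating precursor cells of skeletal muscle. In 3 libraries the cells carried a doxycycline-inducible copy of human DUX4, in 3 an inducible copy of pig DUXC and in 3 inducible GFP, which served as the control, and all were kept for 16 h in 1 µg/mL doxycycline. DUX4 is a double homeobox transcription factor of the early human embryo whose misexpression in skeletal muscle underlies facioscapulohumeral muscular dystrophy, and DUXC is a double homeobox gene of the pig. Total counts were 41220095, 44420895 and 39842081 in the DUX4 libraries, 36580573, 38971217 and 37248713 in the DUXC libraries and 42362395, 39979602 and 40608840 in the GFP libraries. Of 27339 genes, 15956 had enough counts to be tested. The first principal component held 74.1% of the variance and placed the DUXC libraries apart from the others, and the second held 21.6% and placed the DUX4 libraries apart. Levels are given as normalised read counts (CPM), mean ± SD of n = 3 libraries. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels of the transgenes themselves were not analysed here, and the groups rest on the labels.

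In the GFP libraries, genes of fibroblasts and the extracellular matrix were abundant and most genes of the muscle lineage were scarce. The 28 fibroblast and matrix genes had a median of 355 CPM, with 17 of them at 100 CPM or more, and COL1A2 was the most abundant at 19252 ± 554 CPM. Among 32 myogenic regulators and satellite cell genes the median was 0.723 CPM, with 9 at 10 CPM or more and TCF12 the most abundant at 225 CPM. The satellite cell factor PAX7 stood at 0.402 ± 0.0975 CPM and the myogenic factor MYF5 at 0.705 ± 0.256 CPM, and MYOD1 and MYOG had 1 and 6 counts over the 3 libraries. The median was 0.295 CPM over 56 sarcomere and muscle differentiation genes, with 6 at 10 CPM or more and TPM1 at 2984 ± 18.2 CPM, and 69.8 CPM over 14 smooth muscle and pericyte genes. Endothelial, immune cell and adipocyte genes had medians of 0.134, 0.164 and 0.0587 CPM. The 50 cell cycle genes had a median of 10.4 CPM.

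The comparison of DUX4 with GFP asks which pig genes respond to the human factor. Several of the most raised genes had few or no counts in the control. TAC1, the precursor of substance P (chromosome 9, 77197403 to 77206529), had 41.7 ± 3.86 CPM with DUX4 and no count with GFP, at least 1657-fold higher, and RFPL4B, a DUX4 target in human cells (chromosome 1, 78312248 to 78313153), had 17.9 ± 2.41 CPM and rose at least 709-fold. C13H3orf56 (chromosome 13, 72876782 to 72879304) went from 0.0330 ± 0.0373 to 158 ± 13.1 CPM, a log2 fold change of 12.07, and the heat shock gene HSPA6, another DUX4 target in human cells, from 0.532 ± 0.185 to 100.2 ± 23.8 CPM (log2 7.55). Among the 10 most lowered genes were CAPN6, from 17.2 ± 1.21 to 0.114 ± 0.0149 CPM (log2 -7.20), the ferritin receptor gene SCARA5, from 11.7 ± 0.645 to 0.0983 ± 0.0526 CPM (log2 -6.86), the growth factor gene IGF1, from 222 ± 7.33 to 5.20 ± 0.836 CPM (log2 -5.42), and the cartilage matrix gene COMP, from 261 ± 9.04 to 11.4 ± 1.58 CPM (log2 -4.51).

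The other most raised genes by fitted fold change were the fatty acid binding protein gene FABP4, at least 61.7-fold higher, SLITRK6, at least 43.0-fold higher, and MYOZ2, a gene of the muscle Z-disc with a log2 fold change of 8.23. FABP4 and SLITRK6 had no count with GFP, so their rank rests on the fitted value and does not follow from these bounds. FUT9, UBTFL1 and FAM84A had 1 to 3 counts in the control, and their ratios, with 95% counting intervals, were 651 (222 to 3158), 303 (83.5 to 2508) and 296 (52.7 to 11722). Intervals and floors of this kind cover counting error only. TMEM100, with 1 to 3 counts with DUX4, was lower by a ratio of 62.8 (17.01 to 524). SFRP5, PCK1, SV2B, HSD11B1 and SCIN fell, with log2 fold changes of -5.19, -5.07, -5.01, -4.81 and -4.55. The rule for named genes required that all 3 libraries of one group lay above all 3 of the other, so this holds for each of these 20 genes by choice. The largest of their adjusted p-values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which is two-sided, was 1.77e-06, for HSPA6. MYOZ2 lies within the span of SEC24D, and SCARA5, IGF1, HSD11B1 and SCIN overlap other genes, so their counts may hold reads of those genes. FUT9 has no position on an assembled chromosome.

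Among further embryonic genes fixed in advance, the homeobox genes LEUTX and ARGFX had no count with GFP and rose with DUX4, at least 36.9-fold and at least 19.6-fold, and KLF17 rose by a ratio of 25.1 (6.60 to 212). ZSCAN4, a marker of the 2-cell-like state in mouse and a DUX4 target in human cells, had no count with GFP and 0.0162 ± 0.0141 CPM with DUX4 and did not pass the test (adjusted p = 0.178 in edgeR). NANOG had no count in either group. DUXA had 9 counts with DUX4 and none with GFP, below the filter for testing, as were CCNA1 with 6 and 6, SLC34A2 with 1 and 2, POU5F1 with 23 and 14, MYOD1 with 9 and 1 and MYOG with 11 and 6. MYF5 rose to 2.16 ± 0.277 CPM (log2 1.61), and PAX7 stood at 0.568 ± 0.107 CPM and did not pass (adjusted p = 0.153). The cell cycle inhibitor CDKN1A fell from 1177 ± 21.5 to 524 ± 27.3 CPM (log2 -1.17). SMCHD1, a chromatin repressor whose loss contributes to the dystrophy, and UPF1, a factor of nonsense-mediated decay, fell with log2 fold changes of -0.19 and -0.25, both in genes that overlap another.

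All 50 cell cycle genes rose with DUX4, with a median log2 fold change of 2.71, and 45 of them rose at least 2-fold. MKI67, a marker of proliferating cells, went from 14.5 ± 0.664 to 136 ± 7.18 CPM, and the securin gene PTTG1 from 5.89 ± 0.422 to 72.9 ± 3.31 CPM. Lists were compared with all other genes by camera, a two-sided test, with its preset inter-gene correlation, and the adjusted p for the cell cycle list was 1.24e-70 (adjusted p = 0.0201 with an estimated correlation). Of 27 hypoxia genes 22 rose and 1, BNIP3L, fell. The angiogenic factor VEGFA went from 231 ± 8.33 to 713 ± 8.45 CPM and BNIP3 from 145 ± 4.08 to 450.4 ± 4.11 CPM, and the list had adjusted p = 1.77e-12 (0.00820 as adjusted p with an estimated correlation). Smooth muscle and pericyte genes moved down, with 11 of 14 lower and CSPG4 and MCAM higher (adjusted p = 6.77e-11, and adjusted p = 0.0482 with an estimated correlation). Smooth muscle actin ACTA2 fell from 1664 ± 55.4 to 227 ± 10.8 CPM and NOTCH3 from 108 ± 4.34 to 19.5 ± 0.801 CPM. Adjusted over the list alone, the counts of changed members in these lists were the same, at 50, 23 and 13.

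The other 7 lists that passed with DUX4 did so with the preset correlation and not with an estimated one. Of 58 DUX4 targets known from human cells, 22 match a symbol of the count table and 16 were tested, and of these 12 rose and CD34 and ZNF217 fell, with a median log2 fold change of 1.34, or 0.82 with genes near the floor set at their bound (adjusted p = 6.04e-05, and adjusted p = 0.0897 with an estimated correlation). Among them the glucose transporter gene SLC2A3 rose from 93.4 ± 0.511 to 299 ± 6.33 CPM and the mRNA export gene NXF1 from 61.2 ± 2.04 to 123.2 ± 2.70 CPM. Of 54 cleavage-stage genes, active in the first divisions of the embryo, 27 match and 14 were tested, and of these 9 rose and none fell, with a median of 3.18, or 2.65 at the bound (adjusted p = 0.00513, and adjusted p = 0.0897 with an estimated correlation). KLF5 rose from 0.952 ± 0.117 to 12.6 ± 1.28 CPM, while EIF1AD, DPPA3, NLRP5 and DPPA2, like ZSCAN4, did not pass. These 2 lists share members: 10 of the 22 targets and 15 of the 27 cleavage-stage genes in the count table also belong to another list. Fibroblast and matrix genes mostly fell, 20 of 27 with 6 higher (adjusted p = 1.91e-05, and adjusted p = 0.0897 with an estimated correlation), among them DCN from 2109 ± 22.8 to 800.4 ± 39.7 CPM and MFAP5 from 28.2 ± 1.402 to 2.74 ± 0.211 CPM, while DPT rose from 38.4 ± 0.694 to 174 ± 4.44 CPM. Ribosomal protein genes fell by small amounts, 69 of 76, with RPS2 and RPS9 higher and a median of -0.20 (adjusted p = 4.10e-05, and adjusted p = 0.615 with an estimated correlation). The RPS2 call (adjusted p = 0.0279, 0.00289 to 0.229 over the alternatives) was lost without DUX4 replicate 2 or 3, at 0.0793 and 0.119, without GFP replicate 2, at 0.229, with the replicate block, at 0.0502, and with limma-voom, at 0.0668. That of RPS9 (0.0148, 0.000515 to 0.125 over the alternatives) was lost without DUX4 replicate 2, at 0.115, and without GFP replicate 1, at 0.125. Genes of the unfolded protein and integrated stress response rose in 24 of 33 and fell in 8 (adjusted p = 0.000337, and adjusted p = 0.0897 with an estimated correlation), the chaperone HSPA5 going from 1083 ± 7.85 to 1896 ± 16.8 CPM. Heat shock genes rose in 18 of 25, DNAJB1 with a log2 fold change of 1.18, and fell in HSPB7, DNAJB4 and CRYAB (adjusted p = 0.000858, and adjusted p = 0.352 with an estimated correlation). Genes of the p53 pathway fell in 18 of 30 and rose in 7, PLK2 among them with log2 1.57 (adjusted p = 0.0285, and adjusted p = 0.135 with an estimated correlation), and this call was lost without GFP replicate 1, at adjusted p = 0.0746. Adjusted over the list alone, 14 targets, 9 cleavage-stage, 26 fibroblast and matrix, 72 ribosomal protein, 32 stress response, 21 heat shock and 25 p53 pathway genes changed, against 71 ribosomal protein genes and otherwise the same counts over all genes.

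The remaining 20 lists did not pass with DUX4, with adjusted p-values from 0.0796 to 0.951. Of 22 tested pluripotency genes, from 35 in the count table, 12 were higher, TFAP2C with log2 4.34, and KLF4 was lower. Ubiquitin-proteasome genes were higher in 21 of 37 and lower in PSMB4. Both lists passed without DUX4 replicate 1, without each of the DUXC replicates and with the replicate number as a block, with adjusted p-values of 0.0198 to 0.0369 and of 0.00295 to 0.0369. The PSMB4 call (adjusted p = 0.0101, 0.00807 to 0.0665 over the alternatives) was lost with DESeq2's size factors, at 0.0625, library size alone, at 0.0584, and DESeq2, at 0.0665, and without DUX4 replicate 1, at 0.0586, or GFP replicate 3, at 0.0519. Of 25 myogenic regulators 11 rose, SPRY1 and ITGA7 among them, and 7 fell, CDON among them, and of 40 sarcomere genes 15 rose and 10 fell, TPM1 and TPM2 among the latter. Trophectoderm and epithelial genes rose in 10 of 21, HAND1 with log2 3.88, and fell in CLDN4, KRT19 and CLDN7. Germline genes rose in 9 of 24 and fell in SYCP2, CCNI2 and PIWIL4, 1 fewer when adjusted over the list alone. Among markers of other cell types, the endothelial genes KDR, FLT1, PECAM1 and ERG rose and EMCN and EGFL7 fell, immune cell genes rose in 3 of 9, SPI1 and CD68 among them, and fell in CSF1R and ITGAM, and the adipocyte genes FABP4, PPARG and LPL rose and PNPLA2, CEBPA and CIDEA fell. Interferon response genes rose in 11 of 42 and fell in 13, and antigen presentation genes rose in 8 of 24 and fell in 8. The oxidative stress and NRF2 list had 10 of 30 higher and 13 lower, the immediate early and AP-1 list 11 of 28 and 13, and the Wnt pathway list 11 of 29 and 15. Splicing factor genes of the serine/arginine class rose in 11 of 26 and fell in PNISR, SRPK2, SRSF5 and TRA2A, and genes of nonsense-mediated decay and the exon junction rose in 10 of 22 and fell in UPF1, TBL2, SMG1 and DHX34. Cholesterol synthesis genes rose in 9 of 22 and fell in FDFT1, PMVK, HSD17B7 and INSIG1. Apoptosis genes rose in 10 of 26 and fell in 9, chromatin genes rose in 13 of 29 and fell in 9, and TRIM family genes rose in 14 of 42 and fell in 14, or 15 adjusted over the list alone. Elsewhere the counts adjusted over the list alone were the same.

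Over all tested genes, DUX4 changed 10341 (64.8%) at a false discovery rate of 0.05 in edgeR, 5248 of them upward and 5093 downward. At least 2-fold changes were found in 1668 raised and 840 lowered genes, and at least 8-fold changes in 474 and 76. These numbers rest on fitted fold changes and include genes near the floor, such as LOC102167856 with 9 counts, whose bound is 2.89-fold. Without a test, 193 genes of at least 1 CPM in the higher group were at least 8-fold higher with DUX4. The 3 libraries of each group did not overlap for 67.0% of the genes, where chance gives 10%. The 474 genes raised at least 8-fold took 1.26 ± 0.0533% of the counts with DUX4 and 0.0202 ± 0.000452% with GFP.

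The comparison of DUXC with GFP asks the same of the pig's own factor. C13H3orf56 reached 2603 ± 159 CPM with DUXC, a log2 fold change of 16.11. LEUTX, a homeobox gene of the cleavage-stage embryo (chromosome 6, 48240324 to 48248568), had no count with GFP and 108 ± 5.45 CPM with DUXC, at least 4280.1-fold higher, and RFPL4B was at least 1035-fold higher at 26.1 ± 1.84 CPM. MSTN, which encodes the muscle growth inhibitor myostatin (chromosome 15, 94623526 to 94628440), rose from 0.0257 ± 0.0445 to 264 ± 9.31 CPM, a ratio of 10457 (3578 to 50712), and overlaps C15H2orf88. Among the falls, IGF1 went from 222 to 25.6 ± 0.517 CPM (log2 -3.12), the potassium channel subunit gene KCNE4 from 86.8 ± 2.13 to 10.6 ± 0.558 CPM (log2 -3.04), the inhibin gene INHBE from 37.03 ± 1.13 to 4.91 ± 0.635 CPM (log2 -2.92) and smooth muscle actin ACTG2 from 50.5 ± 0.888 to 6.84 ± 0.0771 CPM (log2 -2.88).

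UBTFL1 rose to 139 ± 4.76 CPM, a ratio of 8259 (2286 to 68203), and HELZ2 to 80.1 ± 2.38 CPM, a ratio of 4759 (1317 to 39302). ADGRE1, ACOD1, the serotonin receptor gene HTR1F and the histone gene HIST1H3E had no count with GFP and were at least 937-fold, at least 789.9-fold, at least 611-fold and at least 548-fold higher, the second and the last of them overlapping another gene. CASP14, SV2B, ADAMTS16, GJB2, WNT4 and CHRNA4 fell, with log2 fold changes of -3.91, -3.86, -3.80, -3.44, -3.13 and -2.90. For these 20 genes too the libraries of the 2 groups did not overlap, as the rule required, and the largest adjusted p was 4.27e-11, for C13H3orf56 (edgeR, Benjamini-Hochberg). ZSCAN4 had 1.11 ± 0.145 CPM with DUXC, at least 43.99-fold higher than with GFP, ARGFX was at least 61.7-fold higher, NANOG at least 34.3-fold higher and KLF17 higher by a ratio of 229 (63.2 to 1901). ZSCAN4 overlaps another gene and NANOG is unplaced. DUXA had 19 counts and none with GFP, SLC34A2 29 and 2, CCNA1 2 and 6, POU5F1 15 and 14, MYOD1 4 and 1 and MYOG 19 and 6, below the filter. MYF5 rose to 1.78 ± 0.286 CPM (log2 1.33) and PAX7 to 1.13 ± 0.182 CPM (log2 1.47), and CDKN1A, SMCHD1 and UPF1 fell, with log2 fold changes of -1.26, -0.41 and -0.16. The UPF1 call (adjusted p = 2.55e-05, 5.91e-09 to 0.295 over the alternatives) was lost with library size alone, at 0.295.

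Embryonic gene groups rose with DUXC. Of the 16 tested DUX4 targets of human cells 13 rose and CD34 fell, with a median log2 fold change of 3.43 (adjusted p = 8.95e-11, and adjusted p = 0.0496 with an estimated correlation), NXF1 reaching 969.6 ± 22.9 CPM. Of the 14 tested cleavage-stage genes 12 rose and EIF1AX fell, with a median of 7.85, or 6.93 at the bound (adjusted p = 3.64e-06, and adjusted p = 0.0496 with an estimated correlation), KLF5 reaching 37.9 ± 2.98 CPM. The oxidative stress and NRF2 list fell in 23 of 30 genes and rose in 6 (adjusted p = 5.26e-05, and adjusted p = 0.0496 with an estimated correlation). In it, heme oxygenase HMOX1 fell from 789 ± 16.9 to 224 ± 5.97 CPM and the superoxide dismutase gene SOD2 rose from 54.3 ± 1.86 to 269 ± 23.2 CPM. Hypoxia genes fell in 19 of 27 and rose in 6 (adjusted p = 0.000545, and adjusted p = 0.0496 with an estimated correlation), LDHA falling from 1929 ± 33.0 to 744 ± 10.3 CPM and ADM rising from 29.8 ± 0.448 to 129 ± 7.60 CPM. These 4 lists passed with either correlation. Adjusted over the list alone, 14, 13, 29 and 25 of their members changed, as over all genes.

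A further 13 lists passed with the preset correlation and not with an estimated one. Interferon response genes rose in 39 of 42, 28 of them at least 2-fold, and IFI35 fell (adjusted p = 1.36e-06, and adjusted p = 0.329 with an estimated correlation), IFI44 going from 4.16 ± 0.213 to 50.9 ± 2.74 CPM and OAS2 from 23.6 ± 1.02 to 121 ± 6.06 CPM. Pluripotency genes rose in 20 of 22 and KLF4 fell, with a median of 5.15, or 4.89 at the bound (adjusted p = 0.000137, and adjusted p = 0.124 with an estimated correlation), TBX3 reaching 102 ± 1.85 CPM. Cell cycle genes rose in 40 of 50, with a median of 0.77, and TYMS, RRM2, UHRF1, GINS2 and CDC25A fell (adjusted p = 3.17e-07, and adjusted p = 0.225 with an estimated correlation). The spindle checkpoint gene MAD2L1 went from 16.7 ± 0.824 to 274 ± 6.34 CPM, CKS2 from 11.6 ± 0.449 to 176 ± 11.2 CPM and MKI67 to 25.4 ± 0.766 CPM. Myogenic regulators and satellite cell genes rose in 20 of 25 and fell in MEF2A, MEF2D, ITGA7, NCAM1 and BOC (adjusted p = 0.000137, and adjusted p = 0.0833 with an estimated correlation), the adhesion gene VCAM1 going from 2.75 ± 0.298 to 82.4 ± 3.92 CPM. Serine/arginine splicing factor genes rose in 19 of 26, SRSF3 with log2 1.58, and fell in SRSF1, SRSF9, SRSF10, SRSF12 and SRPK1 (adjusted p = 0.000628, and adjusted p = 0.214 with an estimated correlation). Chromatin genes rose in 15 of 29 and fell in 8, EED with log2 2.28 and EZH2 with 2.87 (adjusted p = 0.0157, and adjusted p = 0.124 with an estimated correlation). Immediate early and AP-1 genes rose in 17 of 28 and fell in 10 (adjusted p = 0.0205, and adjusted p = 0.489 with an estimated correlation), CTGF going from 469 ± 17.2 to 3144 ± 50.1 CPM.

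Markers of fibroblasts and smooth muscle fell with DUXC as well, 19 of 27 against 6 higher (adjusted p = 7.84e-05, and adjusted p = 0.124 with an estimated correlation) and 11 of 14 against SYNPO2, RGS5 and MCAM (adjusted p = 1.13e-05, and adjusted p = 0.114 with an estimated correlation). COL5A1 fell from 2246 ± 61.6 to 646 ± 13.1 CPM and ACTA2 to 355 ± 11.8 CPM, while PDGFRA rose from 373 ± 5.67 to 926 ± 12.96 CPM. Unfolded protein and integrated stress response genes fell in 22 of 33 and rose in 9 (adjusted p = 0.00584, and adjusted p = 0.124 with an estimated correlation), PSAT1 with log2 -1.27 and ATF3 with 2.48. Heat shock genes rose in 14 of 25 and fell in 10 (adjusted p = 0.0212, and adjusted p = 0.443 with an estimated correlation), a call lost without DUX4 replicate 1 or 2, without each DUXC replicate and with the replicate block, at adjusted p-values of 0.0526 to 0.0948. Ribosomal protein genes fell in 54 of 76 and rose in RPL37 (adjusted p = 0.0281, and adjusted p = 0.743 with an estimated correlation), and germline genes rose in 14 of the 24 tested of 49 in the count table, TEX14 with log2 7.47, and fell in SYCP2, TEX15 and MEIOB (adjusted p = 0.0481, and adjusted p = 0.136 with an estimated correlation). Both of these calls were lost with DESeq2's size factors, at 0.0859 and 0.0793, with library size alone, at 0.164 and 0.0935, without GFP replicate 1, at 0.0529 and 0.0608, and without GFP replicate 3, at 0.0716 for each. The rise of RPL37 (adjusted p = 0.0139, 1.84e-08 to 0.288 over the alternatives) was lost without a filter, at 0.288, without DUXC replicate 2, at 0.0556, and without GFP replicate 1 or 2, at 0.106 and 0.0702.

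The other 13 lists did not pass with DUXC, with adjusted p-values from 0.0678 for adipocyte genes to 0.951. Adipocyte genes were higher in 6 of 9, the lipase gene LPL with log2 5.43, and lower in CEBPA. The sarcomere list had 23 of 40 higher, or 24 adjusted over the list alone, and 12 lower. Of 8 endothelial genes PECAM1, TEK, KDR and ESAM rose and FLT1, EMCN, ERG and EGFL7 fell, and of 9 immune cell genes CD14, LYZ, CORO1A, CD79A and CD68 rose and CSF1R and ITGAM fell. Trophectoderm genes rose in 10 of 21 and fell in 8, antigen presentation genes in 8 and 10 of 24 and p53 pathway genes in 12 and 16 of 30. Genes of nonsense-mediated decay rose in 11 of 22 and fell in 8, Wnt pathway genes in 11 and 14 of 29, cholesterol synthesis genes in 10 and 7 of 22 and ubiquitin-proteasome genes in 13 and 17 of 37. Apoptosis genes rose in 8 of 26 and fell in 14, and TRIM family genes rose in 21 of 42 and fell in 17. In all lists but the sarcomere list the counts adjusted over the list alone were the same. PRAME, the 1 measured member of its family, was not tested as a list. PRAME had no count with GFP and 0.497 ± 0.0113 CPM with DUXC, at least 19.7-fold higher.

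Over all tested genes DUXC changed 13165 (82.5%) in edgeR at a false discovery rate of 0.05, 6422 of them upward and 6743 downward. This balance depends on the scaling. More genes rose than fell with library size alone (7268 and 5723), with DESeq2's size factors (6920 and 6118) and with DESeq2 (7564 and 5882). At least 2-fold changes were found in 3400 raised and 1272 lowered genes and at least 8-fold changes in 1419 and 15, again by fitted fold changes. Without a test, 880 genes of at least 1 CPM in the higher group were at least 8-fold higher with DUXC. The groups did not overlap for 83.5% of genes, against 10% by chance. The 1419 genes raised at least 8-fold took 11.3 ± 0.326% of the counts with DUXC and 0.169 ± 0.00237% with GFP. Scaling by library size alone moved the median log2 fold change of all genes by 0.12 in this comparison and by -0.10 between DUX4 and DUXC, and changes of that size depend on the scaling.

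**Figure D1:**
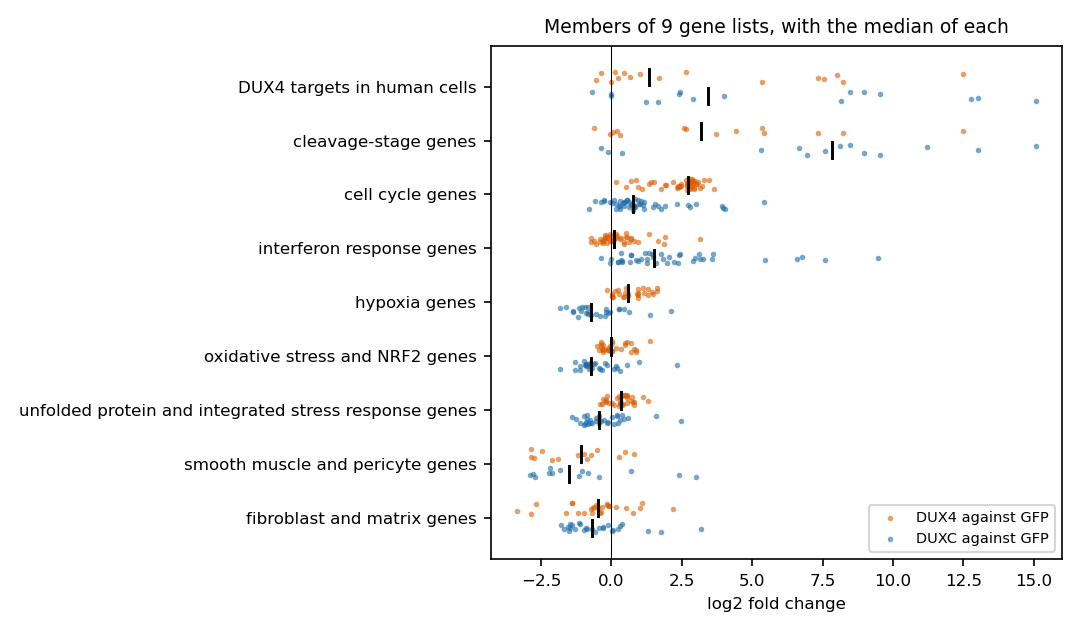
Log2 fold change against GFP (horizontal axis) of each tested member of 9 gene lists (vertical axis), with DUX4 in orange and DUXC in blue and a black bar at the median of each list. Cell cycle genes have a median of 2.71 with DUX4 and 0.77 with DUXC, and interferon response genes 0.07 and 1.52.

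The direct comparison of DUX4 with DUXC asks where the factors differ. HAND1, a transcription factor of heart and placenta, had 9.09 ± 1.21 CPM with DUX4 and 0.0935 ± 0.0550 CPM with DUXC (log2 6.57), and the xenobiotic enzyme CYP1A1 had 56.7 ± 8.29 and 1.04 ± 0.341 CPM (log2 5.76). In the other direction CYP7A1, the rate-limiting enzyme of bile acid synthesis, had 368 ± 12.97 CPM with DUXC and 0.136 ± 0.0733 CPM with DUX4 (log2 -11.35), in a gene that overlaps SDCBP. The potassium channel gene KCNK10 had 40.6 ± 1.93 CPM with DUXC and no count with DUX4, at least 1668-fold higher with DUXC.

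CASP14, RASD2, CARD14, the cholecystokinin gene CCK, P2RY6 and EDNRB were higher with DUX4, with log2 fold changes of 6.01, 5.32, 5.18, 4.90, 4.64 and 4.49. CCR4, TGM6, CD200 and the keratin gene KRT84 had no count with DUX4 and were at least 485-fold, at least 122-fold, at least 106-fold and at least 97.5-fold higher with DUXC, and the prolactin gene PRL and the bone matrix gene IBSP were higher by ratios of 1522 (273 to 60163) and 1003 (179.7 to 39671). The libraries of the 2 groups did not overlap for these 16 genes, as the rule required, and the largest adjusted p was 9.66e-08, for CYP1A1 (edgeR, Benjamini-Hochberg). Embryonic genes were higher with DUXC: LEUTX by a log2 difference of -6.85, ARGFX -1.65 and KLF17 -3.18, ZSCAN4 by a ratio of 68.5 (18.6 to 571) and NANOG at least 35.6-fold. PAX7 was lower with DUX4 (log2 -0.99), while MYF5, at 0.28, did not pass (adjusted p = 0.122) but did without DUX4 replicate 1 (0.0410, with 0.0410 to 0.411 over the alternatives). SMCHD1 differed by 0.22. UPF1 differed by -0.09 (adjusted p = 0.0162, 3.03e-06 to 0.251 over the alternatives), a call lost without a filter, at 0.249, without DUX4 replicate 1, at 0.251, and without DUXC replicate 1, at 0.0732. CDKN1A differed by 0.09 (adjusted p = 0.00614, 9.82e-06 to 0.812 over the alternatives), a difference that was -0.0080 with library size alone. Its call was lost there, at 0.812, with DESeq2's size factors, at 0.223, with at least 1 CPM required, at 0.231, with DESeq2, at 0.190, and without DUX4 replicate 3, at 0.0548.

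Of 50 cell cycle genes 42 were higher with DUX4, with a median log2 difference of 1.63, and 7 higher with DUXC, MAD2L1 and CDC6 among them (adjusted p = 1.67e-14, and adjusted p = 0.147 with an estimated correlation). UHRF1 had 43.7 ± 2.37 CPM with DUX4 and 4.82 ± 0.123 CPM with DUXC. Hypoxia genes were higher with DUX4 in 22 of 27, LDHA at 3664 ± 8.83 CPM, and higher with DUXC in ADM, PFKFB4, KDM3A and HK2 (adjusted p = 1.98e-09, and adjusted p = 0.0108 with an estimated correlation). Stress response genes were higher with DUX4 in 25 of 33 and lower in ATF3, PPP1R15A, HERPUD1, DNAJC3 and ERN1 (adjusted p = 8.05e-06, and adjusted p = 0.0579 with an estimated correlation). NRF2 genes were higher in 24 of 30, HMOX1 at 2026 ± 109 CPM, and lower in SOD2, NFE2L2 and TXNRD1 (adjusted p = 2.18e-05, and adjusted p = 0.0579 with an estimated correlation). Interferon response genes were higher with DUXC in 39 of 42 and with DUX4 in none (adjusted p = 2.43e-07, and adjusted p = 0.388 with an estimated correlation). Higher with DUXC were also 13 of 16 DUX4 targets, with PITX1 the other way (adjusted p = 2.81e-06, and adjusted p = 0.114 with an estimated correlation), and 12 of 14 cleavage-stage genes, with EIF1AX the other way (adjusted p = 0.000683, and adjusted p = 0.114 with an estimated correlation). The same held for 17 of 22 tested pluripotency genes, with LIN28B, KLF4, NR5A2 and DNMT3B the other way (adjusted p = 0.00497, and adjusted p = 0.248 with an estimated correlation). It also held for 20 of 25 myogenic regulators, with NCAM1, ITGA7, MEF2A and MEF2D the other way (adjusted p = 0.00166, and adjusted p = 0.147 with an estimated correlation). Splicing factor genes were higher with DUXC in 19 of 26 and lower in SRSF1, SRSF9, SRSF10, SRSF12 and SRRM2 (adjusted p = 0.0120, and adjusted p = 0.388 with an estimated correlation). The hypoxia list alone passed with an estimated correlation, the counts adjusted over the list alone were the same, and the other 20 lists had adjusted p-values from 0.104 to 0.911.

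Over all tested genes, 13150 (82.4%) differed between DUX4 and DUXC in edgeR at a false discovery rate of 0.05, 6515 higher and 6635 lower with DUX4. The near-even split depends on the scaling. Higher and lower genes numbered 5753 and 7379 with library size alone, 6130 and 7014 with DESeq2's size factors and 5884 and 7238 with DESeq2. Differences of at least 2-fold were found in 1568 and 3309 genes and of at least 8-fold in 70 and 1039. The groups did not overlap for 83.0% of genes, against 10% by chance.

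**Figure D2:**
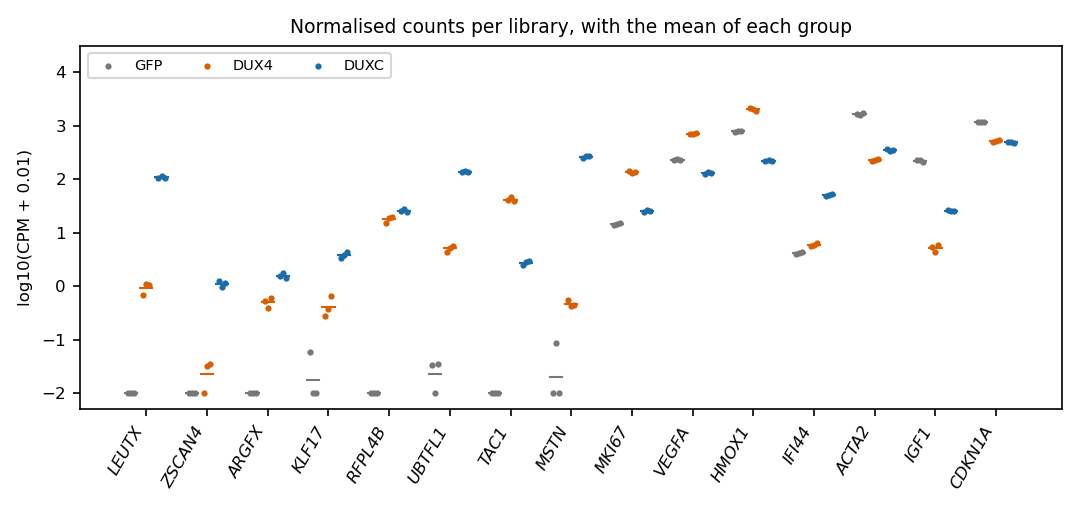
Normalised counts of 15 named genes in each of the 9 libraries, on a log10 scale after adding 0.01 CPM, with a bar at the mean of each group. LEUTX lies at 0 CPM in the GFP libraries, at 0.930 CPM on average with DUX4 and at 108 CPM with DUXC, and MKI67 is higher with DUX4 than with DUXC.

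How far the transgenes act on the same genes was asked from the overlap of the lists against GFP. C13H3orf56, RFPL4B and UBTFL1 were among the 10 most raised genes with each transgene, and IGF1 and SV2B among the 10 most lowered with each. Of 1668 genes raised at least 2-fold by DUX4, 1102 (66.1%) were raised at least 2-fold by DUXC, where independent lists would share 355. Of 840 genes lowered at least 2-fold, 272 (32.4%) were shared, where independent lists would share 67.0. Among genes raised at least 8-fold by DUX4, 397 of 474 (83.8%) were raised at least 8-fold by DUXC, against 42.2 for independent lists. These fitted fold changes include genes near the floor. Independent lists treat all tested genes alike and are not matched on the GFP level. Genes scarce with GFP passed the filter only through a transgene, so the excess of shared raised genes may be overstated, by an amount not measured. Opposite changes of at least 2-fold were found in 58 genes raised by DUX4 and lowered by DUXC and in 106 the other way. Of the 1102 shared raised genes 844 had the larger fold change with DUXC, and of the 272 shared lowered genes 99 did. At any size, 2682 genes rose with both, 3110 fell with both, 1819 rose with DUX4 and fell with DUXC and 1256 did the reverse, against 2112, 2152, 2218 and 2050 for independent lists. Whether more genes rose or fell with both depends on the scaling. The numbers were 3114 and 2541 with library size alone, 2993 and 2677 with DESeq2's size factors and 2784 and 2384 with DESeq2.

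Across the 15956 genes, which are not independent replicates, the log2 fold changes of the transgenes had a Pearson r of 0.645 and a Spearman rho of 0.361. Both comparisons use the same GFP libraries, which by itself gives a correlation: groups simulated without any effect and sharing 3 controls gave a mean r of 0.501, a rho of 0.450 and 66.7% of genes with the same sign, against 60.5% in the data. The covariance was 1.76 in the data and 0.00977 in the simulations, and the simulations shared on average 0 raised and 0.1 lowered genes. A correlation does not depend on the size of the changes, so the simulated r is not the part of 0.645 that shared controls give. By covariance, shared controls gave little in the simulations. The simulations held no real changes, however, and the filter removed genes scarce with GFP from them. They therefore do not show how the shared controls act on genes that change. The 3 control libraries do not divide into sets of at least 2 for each comparison, so they were not split. Part of the excess in the overlap may come from the shared controls.

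**Figure D3:**
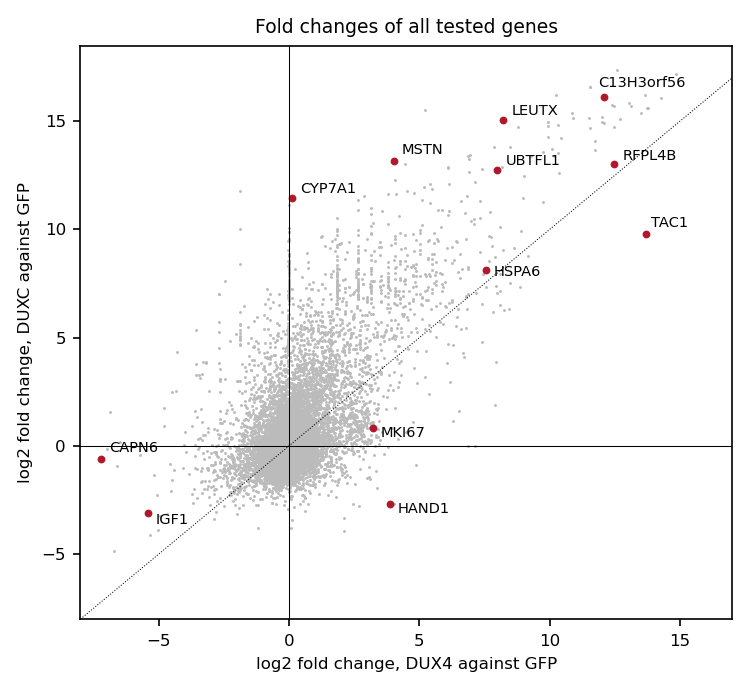
Log2 fold change of each of the 15956 tested genes with DUXC against GFP (vertical axis) and with DUX4 against GFP (horizontal axis), with named genes in red and a dotted line where both are equal. C13H3orf56 and RFPL4B are high with both, TAC1 and HAND1 lie below the line and CYP7A1 lies near 0 for DUX4 at 0.12.

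The most abundant responders include genes without a symbol of their own that lie next to each other in the order of tested genes, chosen here after their values were seen. On chromosome 6, from 72732006 to 72892480, 9 neighbouring genes listed only under locus identifiers rose at least 8-fold with each transgene, and their levels summed to 0.940 CPM with GFP, 4077 with DUX4 and 31341 with DUXC. LOC100737881, the first of them, went from 0.157 ± 0.189 CPM to 667 ± 59.2 with DUX4 and 6219 ± 199.8 with DUXC. On chromosome 9, from 22965206 to 23161825, 8 neighbours from LOC100623167 to NAALAD2, UBTFL1 among them, summed to 0.527, 3620 and 15374 CPM. Runs of 5 genes on chromosome 2 (71964699 to 72305925, ending with ADGRE1) and on chromosome 8 (44007543 to 44102219) summed to 0.0657, 1093 and 3871 CPM and to 0.268, 276 and 3482 CPM. The families of these genes were not identified here, and near-identical copies may share reads, so the level of a single copy is less certain than the sum.

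**Figure D4:**
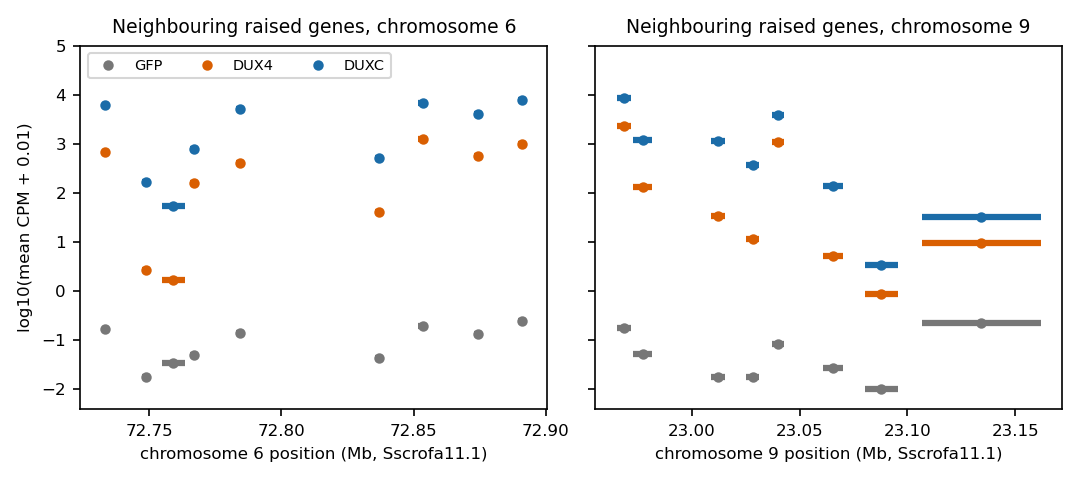
Mean normalised counts, on a log10 scale after adding 0.01 CPM, of the neighbouring raised genes against their position on chromosome 6 and on chromosome 9 of Sscrofa11.1, with GFP in grey, DUX4 in orange and DUXC in blue and a horizontal line over the span of each gene. The genes sum to 0.940 CPM with GFP on chromosome 6 and to 31341 CPM with DUXC.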

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

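All of the alternatives were planned. The numbers of changed genes were 2508, 4672 and 4877 for DUX4 against GFP, DUXC against GFP and DUX4 against DUXC with a log2 fold change of at least 1 required as well, and 1656, 3656 and 3796 when tested with glmTreat against a 2-fold change, which asks for more than a change of any size. Genes raised and lowered by both numbered 1102 and 272 at a log2 fold change of at least 1. The correlation of the fold changes was 0.573 without a filter, 0.668 with at least 1 CPM in 3 libraries, 0.601 with DESeq2, 0.600 with limma-voom and 0.622 to 0.666 with each library left out. The lists called numbered 3, 4 and 1 with an estimated correlation and 26, 28 and 26 with fry, which tests another question. Of results that passed in the main analysis or in the alternative, those opposite in direction were CDKN1A between DUX4 and DUXC with library size only (log2 -0.0080 against 0.09), the TRIM family for DUX4 with fry (adjusted p = 0.00321) and the ubiquitin-proteasome list for DUXC with fry (adjusted p = 0.0155), and the cause was not tested. With each library left out the counts were 9791 to 10394, 12916 to 13551 and 12919 to 13446, with 2508 to 2638 raised and 2909 to 3068 lowered by both, and 9 to 12, 15 to 17 and 10 lists called. With the replicate block they were 10272, 13125 and 13094, with 2661 and 3090 shared, a correlation of 0.645 and 12, 16 and 10 lists. Of 415 results for named genes 9 changed direction or call in at least 1 alternative, and of 90 list results 72 did. The stricter filter gave a value for 398 of the 415. Library size alone moved the median log2 fold change by 0.12 for DUXC against GFP and by -0.10 for DUX4 against DUXC. Genes near the floor of 3 counts are limited by depth, so a difference such as that of ZSCAN4 between DUX4 and GFP was not detectable here.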

Other observations

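The tests of neighbouring genes, of the cell cycle genes and of the sizes of the responses were chosen after the results were seen, and those of the splits before.

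Further groups of neighbouring genes rose with DUXC, and their genes are named here after their values were seen. On chromosome 7, from 20774135 to 20875411, 9 neighbours that include the histone genes HIST1H2BD and HIST1H3E summed to 10.6 CPM with GFP, 16.6 with DUX4 and 1063 with DUXC. The chromosome 5 run from KRT84 to KRT8, which holds the keratin genes KRT6A, KRT3 and KRT79, had no count with GFP and summed to 0.0901 CPM with DUX4 and 9.09 with DUXC. The kallikrein genes KLK15, KLK4, KLK5, KLK6 and KLK7 summed to 0.430, 0.548 and 5.79 CPM, the matrix metalloproteinase genes MMP3, MMP12 and MMP13 with a further neighbour to 0.0506, 1.70 and 153 CPM, and GDF3, DPPA3 and NANOGNB, genes of pluripotent and germ cells, with a further neighbour to 0.0171, 0.462 and 19.5 CPM. HIST1H2BD fell with DUX4, from 8.36 to 5.81 CPM, MMP12 held most of the DUXC sum of its run, at 0.0424, 0.769 and 145 CPM, and MMP3 was higher with DUX4 than with DUXC, at 0.780 and 0.414 CPM (adjusted p = 0.00517). In a chromosome 8 run that rose with both, the long noncoding RNA gene LOC106507819 had 0.152 CPM with GFP, 47.6 with DUX4 and 12.03 with DUXC. Of its neighbours, STATH and ODAM were higher with DUX4 (log2 2.60 and 1.62), CSN1S1 was higher with DUXC (log2 -1.42, adjusted p = 0.00117) and SULT1E1 did not differ between them (adjusted p = 0.225). Long noncoding RNA genes made up 192 of 1412 genes raised at least 8-fold by DUXC (13.6%) and 7.92% of tested genes (Fisher's exact test, two-sided, odds ratio 1.98, p = 1.76e-14), but compared with genes of like GFP level the odds ratio was 0.469 (Mantel-Haenszel test, two-sided, p = 2.30e-10). With DUX4 they made up 44 of 473 (9.30%, Fisher's exact test, p = 0.260), with an odds ratio of 0.393 at like GFP level (Mantel-Haenszel test, p = 4.36e-08). All 4 tests cover tested genes only, and a gene scarce with GFP passed the filter only through its counts with a transgene. These odds ratios therefore depend on the filter and do not show how readily long noncoding RNA genes respond.

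In the order of tested genes, those raised at least 8-fold lay next to each other more often than draws of genes of like GFP level. Genes below the filter are not in this order, so some may lie between 2 neighbours. The draws do not account for their removal. With DUXC, 500 of 1392 placed genes (35.9%) had a raised neighbour, making 312 neighbouring pairs against a mean of 185 and a highest of 230 in 100000 matched draws (one-sided permutation p = 1e-05, the smallest they can give), and with DUX4 80 pairs against a mean of 21.7 and a highest of 43, so the low control level of such genes is not enough to give these counts among tested genes. Restricted to genes of at least 1 CPM with the transgene, the pairs were 144 against a highest of 93 and 31 against a highest of 14. Reads of 1 active copy counted for its neighbours would give a run 1 ratio of DUX4 to DUXC, but in 4 of 4 runs with 4 or more genes under locus identifiers of at least 1 CPM with both transgenes, the log2 ratios of these genes spanned 2.12 to 3.59. The spans argue only against 1 source copy for a whole run. Several genes of a run had close ratios: on chromosome 8 from 44007543 to 44102219 they were -6.48, -6.36, -6.27, -3.36 and -3.22. Sharing of reads from several source copies therefore stays open in these runs. A further run lies close by on chromosome 8, from 44145897 to 44197510, so the 4 runs may not be separate loci. In the 293 other pairs reads of 1 copy and of several cannot be told apart without the reads. A candidate explanation is a response of gene clusters to DUXC, and of some of them also to DUX4. This explanation was found and tested on the same data.

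Cell cycle genes were higher with DUX4 in 50 of 50, and a larger share of cycling cells in the DUX4 libraries, a hypothesis found on the same data, was not tested. With library size alone the median log2 fold change of the list was 2.73, against 2.71 with TMM. That change of scaling moved the fold changes of all genes by a median of 0.024, so it could not have removed the rise. Scaling moves all genes of a library alike, and the median over all tested genes was 0.0035 with TMM. Library scaling therefore does not account for the rise of the list relative to other genes. In 40 of the 50 genes both transgenes were above GFP, as a slow growth of the GFP cultures that is not due to the transgene would also give, so an effect of the transgenes and such a state of the cultures cannot be told apart, because each group has 1 transgene and the labels give no growth measure. The fold changes of the members had an SD of 0.80 with DUX4 and 1.28 with DUXC.

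DUXC changed more genes than DUX4 and raised more at least 8-fold, 1419 against 474, while DUX4 lowered more at least 8-fold, 76 against 15, and 99 of the 272 genes lowered at least 2-fold by both changed more with DUXC. Depth does not account for the larger numbers with DUXC, since the DUXC libraries had 0.899 times the counts of the DUX4 libraries. A larger spread between the DUX4 libraries does not account for the larger number raised at least 8-fold. Without any test, 880 genes of at least 1 CPM were at least 8-fold higher with DUXC and 193 with DUX4, a ratio of 4.56. Pairs of DUX4 libraries did differ more, with a chi-square per degree of freedom of 7.06 to 18.6, against 2.66 to 4.65 for pairs within the other groups. The part of this spread in the number of changed genes of any size was not tested. A weaker form of 1 response may explain part of the difference. Of 1668 genes raised by DUX4, 539 (32.3%) were at least 2-fold higher with DUX4 than with DUXC, 35 of them in the cell cycle list. Of the 539, 323 were not raised by DUXC. A weaker form of 1 response does not explain the 539 if every gene rises steadily with activity. If genes can respond more at a lower activity, these values cannot decide, because activity was not measured. For the 631 genes (37.8%) at least 2-fold higher with DUXC, a lower amount of DUX4 and a weaker action of it cannot be told apart, because the amounts of the transgenes are not measured here. A difference between the factors themselves stays open and was not tested.

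The 6 libraries of each comparison can be divided in 10 ways, too few for a share under 0.05. The real division gave 10341, 13165 and 13150 changed genes for DUX4 against GFP, DUXC against GFP and DUX4 against DUXC, and the highest of the others was 0 in each (edgeR; at most 374, 62 and 66 genes at an unadjusted p under 0.05), so that 1 of 10 divisions gave as many. For the lists, the real division called 10, 17 and 10 and the highest of the others 8, 13 and 10, so that 1, 1 and 4 of 10 divisions gave as many. Each other division sets 2 libraries of one group and 1 of the other against the rest, so it keeps part of the real difference. It also puts real differences inside each set, which widens the spread and lowers the number of genes called. The 0 genes of the other divisions therefore do not measure what chance would give.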
